A study of Mus musculus with 30 samples.

How the data were processed

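Total RNA from 30 samples of mouse hippocampus was hybridised to the mouse Metabolic Pathways panel of the NanoString nCounter, an assay that counts colour-coded reporter probes bound to each target RNA without amplification. Per the labels' protocols, RNA was purified with a PureLink RNA Mini Kit and 200 ng per sample were analysed. The mice were of 2 genotypes. APP/PSEN1/mt-Keima mice, called AD here as in the labels, carry human transgenes that drive amyloid deposition together with mt-Keima, a fluorescent reporter of mitophagy that is targeted to mitochondria. WT/mt-Keima mice, called WT, carry the reporter alone. Samples were placed in groups by the genotype and age in their labels, which gave 10 groups of 3 samples, 1 for each genotype at 9, 15, 25, 30 and 50 weeks.

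The deposited table holds a linear signal per probe and sample that is never negative. The labels name nCounter Advanced Analysis as the authors' tool, while the normalization, the treatment of background and the housekeeping probes are not given in the sources used here. In every sample the deposited signal values were whole multiples of 1 step, which fits counts multiplied by 1 factor per sample by the authors. Dividing by that step gave whole counts for 100% of values in each sample, with a tolerance of 0.1 count and a largest distance of 0.011 count. A floor of 1.00 stood in place of 10 values. The table held no control probes by name, so the signal over background was not measured here. The 768 probes carry RefSeq accessions as identifiers. Of these, 756 were matched to a gene symbol through a RefSeq gene table of the assembly GRCm38.p6, used for names only, and 12 were left under their accession. App, Psen1, Trem2, Gfap and Pink1 were not on the panel.

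The recovered counts per sample ranged from 1327148 to 1831301 at 9 to 30 weeks (median 1596975.5) and from 518510 to 776144 at 50 weeks (median 707873.5), a ratio of medians of 2.26. One count was worth 0.784 to 1.06 units of signal at 9 to 30 weeks and 1.87 to 2.73 at 50 weeks, so low values were measured more coarsely at 50 weeks. Each of the 30 pairs of replicates of a group differed by more than counting noise (chi-square per degree of freedom from 1.88 to 97.1), so every sample was counted once.

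Because the values were linear and already scaled, log2(value + 1) was tested with limma 3.58.1 in R 4.3.3, with the 10 groups in a single fit of 20 residual degrees of freedom, a variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment over the 768 probes. A probe was called at an adjusted p below 0.05. Fold changes refer to the log2(value + 1) scale, which understates changes of low values. The contrasts, fixed before the data were examined, were the AD minus WT difference averaged over the 5 ages and at each age, the linear change with age in each genotype per 10 weeks, the difference between these slopes, and an F test of the 4 interaction contrasts of genotype and age. Levels are given as mean ± SD of 3 samples and log2 changes as estimate ± SE.

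Of the 39 gene lists fixed before the data were examined, 29 had at least 3 measured genes and were tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over the 29 lists. The camera test was repeated with the correlation estimated from the data, and fry, which tests whether the genes of a list move on balance in 1 direction, was run on the same lists. The genes named for each comparison followed a rule fixed beforehand. For the averaged difference these were up to 12 rising and 12 falling called genes with the largest change, or the 10 smallest p where fewer than 10 passed. For the other contrasts they were up to 6 in each direction, the 10 smallest p of the F test, or the 3 smallest p where none passed. For each list described they were up to 4 called members, or the 2 with the smallest p. Mapt, Apoe and Prkn were named in any case. Genes named outside this rule are said to have been chosen after their values were seen.

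Alternatives were 3 other scalings (centring on the median, centring on 22 housekeeping probes, quantile normalization), pseudocounts of 10 and 0.5, omission of the 25% of probes with the lowest mean, which left 576 probes, no variance trend, sex as a covariate, the replicate number as a block, sample weights, fits to the 6 samples of an age, 50 minus 9 weeks in place of the slope, and omission of each of the 30 samples in turn. Alternatives added after the data had been seen were the edgeR 4.0.16 quasi-likelihood test on the recovered counts, covariates for the level of choroid plexus genes (mean log2 value of Ttr and Folr1, or Ttr on the linear scale) alone or with Eomes, omission of the 50-week samples, and recovered counts thinned to 518510 per sample. A DESeq2 fit had been planned only for raw counts and was not run.

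The limma and camera steps were first tested on data simulated from the mean of each gene over all samples and its spread. In these data 100 of 768 genes were changed by 1 and 100 by 0.5 on the log2 scale. For the slopes these were the changes from 9 to 50 weeks. For a change of 1 the averaged comparison recovered 97% of genes, the comparison at 9 weeks 77% and that at 50 weeks 76%. For a change of 0.5 the values were 83%, 60% and 53%. The slope difference recovered 62% and 44% and the WT slope 85% and 69%. In these simulations 13 of 568 unchanged genes were called in the averaged comparison, 3 at 9 weeks and 11 at 50 weeks. For the slope difference 5 were called and for the WT slope 5. In a further simulation the lysosome list was shifted by 0.5 in AD samples at 50 weeks. That list was called by camera, with an estimated correlation and by fry. Camera also called 1 other list. Some other lists share genes with the lysosome list and carry part of its shift, so this call need not be false. Simulated data without any change gave 0 calls of genes or lists. Each gene was drawn independently in all these simulations, without variation that genes share between samples. They therefore cannot show how many false calls of genes or lists such shared variation gives. Nor can they show how often an estimated correlation would then miss a shifted list.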

Results

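Expression of metabolic and immune genes was compared between the hippocampus of APP/PSEN1/mt-Keima mice (AD) and WT/mt-Keima mice (WT) at 5 ages, as part of a study of mitophagy in the brain of this amyloid model. The data comprised 30 samples, 3 for each genotype at 9, 15, 25, 30 and 50 weeks, measured with 768 nCounter probes. The labels do not state that each sample came from a separate mouse, so the p-values measure only the spread between these samples. The samples were 9 females and 21 males, with 5 females among WT and 4 among AD samples. At 15 weeks 2 WT but 0 AD samples were female, and at 30 weeks 0 WT samples but 1 AD sample. The recovered counts per sample were 1327148 to 1831301 at 9 to 30 weeks and 518510 to 776144 at 50 weeks, so the oldest samples were read at less depth in both genotypes. No gene differed by sex within groups in limma (47 at an unadjusted p below 0.05). This was tested with limma alone.

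Averaged over the 5 ages, a pair of lysosomal genes was higher in AD than in WT hippocampus, and 0 genes were lower. Cd68, a lysosomal glycoprotein of microglia and macrophages, rose by 0.30 ± 0.05 on the log2 scale (1.23-fold, adjusted p = 0.00074 by limma). It was above the WT mean of its age in 10 of 15 AD samples and below it in 5. Ctsd, the lysosomal protease cathepsin D, rose by 0.33 ± 0.07 (1.26-fold, adjusted p = 0.029) and was above the WT mean in 13 of 15 AD samples. The 8 genes with the next smallest p did not pass. The largest of these estimates were 0.39 for the chemokine Ccl4 and 0.37 for Cd14, a co-receptor for lipopolysaccharide (both adjusted p = 0.16), and 0.35 for Bcl2a1a (adjusted p = 0.1). Estimates were smaller for Ctsz (0.33), Ly86 (0.27), Myd88 (0.26) and Hexa (0.15). Mtor, the kinase of the mTOR complexes, had an estimate of -0.09 and lay below the WT mean in 15 of 15 AD samples (adjusted p = 0.16). These genes were picked by their p on the same samples, and AD samples of an age share a WT mean. The counts of samples above or below it are therefore no further evidence. Mapt (-0.01), Apoe (0.02) and Prkn (-0.07), which encode tau, apolipoprotein E and the mitophagy ligase parkin, did not pass.

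Of the 15 measured genes of the plaque-associated microglia list, 2 rose (Cd68 and Ctsd) and 13 did not pass (11 passed when adjusted over the list alone). The list shifted upward with a median of 0.22 (adjusted p = 1.8e-08 by camera, adjusted p = 0.12 with an estimated correlation). The lysosome list, which shares 9 genes with it, had the same 2 of 16 genes called (8 adjusted over the list alone), with a median of 0.15 (adjusted p = 8.3e-08, adjusted p = 0.17 with an estimated correlation). In the list of Toll-like receptor and NF-kB signalling 0 of 11 genes passed (2 adjusted over the list alone), with a median of 0.09 (adjusted p = 0.013, adjusted p = 0.42 with an estimated correlation). Subunits of mitochondrial complexes II to IV and cytochrome c shifted downward by a median of -0.04 (adjusted p = 7e-04, adjusted p = 0.42 with an estimated correlation). None of its 15 genes passed, and 0 passed when adjusted over the list alone; Cox6a1 had an estimate of -0.07 and Cox5b of -0.08. The TCA cycle list had a median of -0.05 (adjusted p = 0.037, adjusted p = 0.54 with an estimated correlation) with 0 of 21 genes called (0 adjusted over the list alone), Cs being at -0.10 and Sdhb at -0.08. No list call of camera in any comparison held with an estimated correlation. The fry test called the plaque-associated microglia and lysosome lists for the averaged difference, at 30 weeks and for the AD slope, the former at 50 weeks, and the endothelium list for the WT slope. It called none of the other lists called by camera. The list of autophagy and mitophagy genes (8 measured) had a median of 0.01 with a mean of 0 (adjusted p = 0.84), and 0 of its genes passed (0 adjusted over the list alone). Averaged over ages Ttr, a choroid plexus gene named after its values were seen, had an estimate of 1.77 ± 1.02 (adjusted p = 0.6), and Ctsd moved with the choroid plexus level within groups. With that level as a covariate Ctsd stood at 0.23 ± 0.04 (adjusted p = 0.0014), the plaque-associated microglia list at 0.12 and the lysosome list at 0.11, all still called, while the lists of Toll-like receptor and NF-kB signalling and the TCA cycle were not. Both of these lists and complexes II to IV were lost with quantile normalization and with choroid plexus and Eomes covariates. The Toll-like receptor and TCA cycle lists were lost without the 50-week samples. The TCA cycle list was further lost without the 25% of probes with the lowest mean, with sex as a covariate and with thinned counts. It was also lost without WT 9 weeks replicate 2, WT 15 weeks replicate 3, WT 25 weeks replicate 1, WT 30 weeks replicates 1 or 3, AD 9 weeks replicate 3, AD 15 weeks replicates 2 or 3, AD 25 weeks replicate 2, AD 30 weeks replicate 3 or AD 50 weeks replicate 3 (adjusted p up to 0.16). With sample weights 12 genes passed. Without the 50-week samples 0 genes passed, with adjusted p = 0.44 for Cd68 and 0.39 for Ctsd. The call of Ctsd was also lost without a variance trend (adjusted p = 0.061) and on omission of any of 17 of the 30 samples (adjusted p up to 0.075), while omission of WT 50 weeks replicate 1 or AD 9 weeks replicate 3 raised the count to 4.

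**Figure D1:**
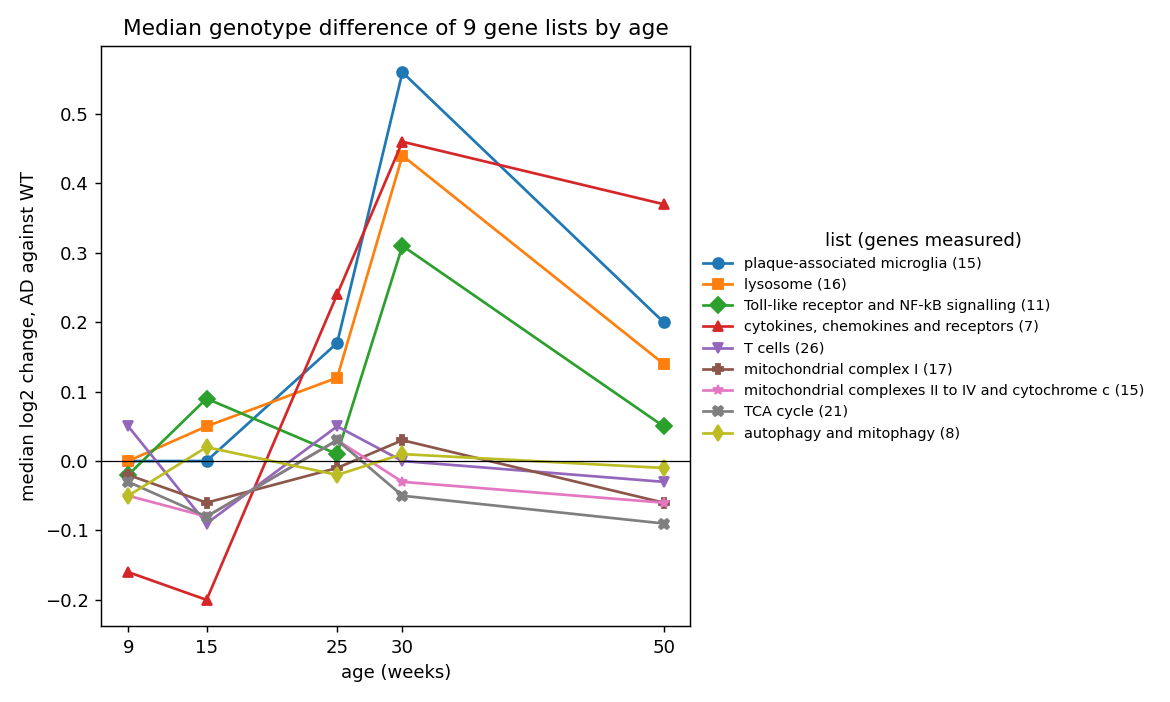
Median log2 change of AD against WT for 9 gene lists (vertical axis) at each age in weeks (horizontal axis), each line being a list with its number of measured genes in brackets. The plaque-associated microglia and lysosome lists lie at 0.56 and 0.44 at 30 weeks and at 0.20 and 0.14 at 50 weeks.

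At 9 weeks no gene passed in limma (8 at an unadjusted p below 0.05, 0 by edgeR). The smallest p belonged to Hdc, which makes histamine, with 14.6 ± 2.25 units in WT and 24.1 ± 1.96 in AD samples (SD, n = 3), a difference of 0.69 ± 0.23. Adora2a, a receptor for adenosine, differed by 0.52 ± 0.19. Cd68 had a lower estimate in AD at this age (-0.28 ± 0.10), with 326 ± 50.0 units in WT and 267 ± 5.31 in AD samples. All 3 had an adjusted p of 0.98. The list of neutrophil and mast cell genes shifted upward by a median of 0.39 (adjusted p = 0.00054 by camera, adjusted p = 0.078 with an estimated correlation), with 0 of 7 genes called (1 adjusted over the list alone), Hdc and the formyl peptide receptor Fpr1 (0.55 ± 0.23) leading. Mean levels of its genes in WT samples ran from 6.48 units for Cpa3 to 39.1 for Csf3r, both named after their values were seen. Subunits of complexes II to IV and cytochrome c shifted by a median of -0.05 (adjusted p = 0.04, adjusted p = 0.97 with an estimated correlation), with 0 of 15 called (0 adjusted over the list alone) and estimates of -0.09 for Cox6a1 and -0.10 for Cox7c. The neutrophil and mast cell list lost its call with counts thinned to the lowest total (adjusted p = 0.12) and had too few genes to be tested without the 25% of probes with the lowest mean. The list of complexes II to IV was no longer called in either of these, with median centring, quantile normalization or a choroid plexus covariate, or without any of WT 9 weeks replicates 2 or 3, AD 9 weeks replicates 1 or 3 and AD 25 weeks replicate 2 (adjusted p up to 0.67). Mapt (-0.06), Apoe (0.00) and Prkn (-0.14) did not pass.

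At 15 weeks no gene passed either (28 at an unadjusted p below 0.05, 0 by edgeR). Srebf2, a transcription factor of cholesterol synthesis, had an estimate of 0.17 ± 0.05, the intracellular receptor Nod2 of -0.92 ± 0.28 at a low level (18.7 ± 3.07 against 9.4 ± 1.21 units), and Hif1a of -0.22 ± 0.08, each with an adjusted p of 0.99. Complexes II to IV and cytochrome c again shifted downward, with a median of -0.08 (adjusted p = 0.0018 by camera, adjusted p = 0.95 with an estimated correlation) and 0 of 15 genes called (0 adjusted over the list alone). The estimates were -0.11 for Cox7c and -0.12 for Sdhb. The 4 measured genes of epigenetic regulation shifted upward by a median of 0.13 (adjusted p = 0.043, adjusted p = 0.52 with an estimated correlation), with 0 called (0 adjusted over the list alone), Nsd1 at 0.10 and Tet2 at 0.15. Neither list was called with median centring (0 lists), quantile normalization (0 lists) or without WT 15 weeks replicate 3 (0 lists). The epigenetic list was also lost with housekeeping centring, sex as a covariate, thinned counts or choroid plexus and Eomes covariates, and without WT 15 weeks replicate 1, AD 15 weeks replicates 1 or 2, WT 50 weeks replicate 1 or AD 30 weeks replicate 2 (adjusted p up to 0.57). Mapt (0.01), Apoe (0.00) and Prkn (0.14) did not pass.

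At 25 weeks the count was 0 in limma (40 at an unadjusted p below 0.05, 0 by edgeR), and 0 of the 29 lists were called. With sample weights 1 gene passed. The smallest p belonged to Mapk8ip1, a scaffold of JNK signalling, with 3306 ± 213 units in WT and 2751 ± 184 in AD samples (log2 change -0.27 ± 0.06, adjusted p = 0.14). Pik3r2, a regulatory subunit of PI3 kinase, had an estimate of -0.30 ± 0.08 (adjusted p = 0.26) and Srebf2 of 0.15 ± 0.05 (adjusted p = 0.74). For each of these 3 genes the AD samples lay wholly above or wholly below the WT samples, as chance gives for 10% of unselected genes with 3 samples against 3. They were picked by their p on the same samples, so the separation is no further evidence. Cd68, named here after its values were seen, stood at 0.30 ± 0.10 (adjusted p = 0.74). Mapt (0.04), Apoe (-0.05) and Prkn (-0.09) did not pass.

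At 30 weeks Cd68 rose in AD hippocampus and was the only gene called (98 genes were at an unadjusted p below 0.05, and 1 passed by edgeR), although sample weights gave 31 genes, 29 rising and 2 falling. Its level was 323 ± 49.9 units in WT and 474 ± 36.9 in AD samples (SD, n = 3), a log2 change of 0.56 ± 0.10 or 1.48-fold (adjusted p = 0.012 by limma), and each of the 3 AD samples was above every WT sample. Cd68 was called on these same samples, so the separation is no further evidence. In the plaque-associated microglia list 1 of 15 genes rose (10 adjusted over the list alone), with a median of 0.56 (adjusted p = 1.1e-07 by camera, adjusted p = 0.17 with an estimated correlation). The lysosome list had 1 of 16 genes called (10 adjusted over the list alone) and a median of 0.44 (adjusted p = 1.1e-07, adjusted p = 0.18 with an estimated correlation). Ctsd, named after its values were seen, was at 0.70 ± 0.15 (adjusted p = 0.052). Antigen presentation genes shifted upward by a median of 0.44 (adjusted p = 0.0083, adjusted p = 0.33 with an estimated correlation), with 0 of 13 called (1 adjusted over the list alone), the protease Ctss being at 0.62 ± 0.18 and the MHC class I gene H2-M3 at 0.44 ± 0.19. Genes of Toll-like receptor and NF-kB signalling had a median of 0.31 (adjusted p = 0.0077, adjusted p = 0.33 with an estimated correlation), with 0 of 11 called (1 adjusted over the list alone), Cd14 at 0.87 ± 0.22 and Myd88 at 0.41 ± 0.17.

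Metabolic lists also shifted at 30 weeks, with 0 genes called in each, both over all genes and adjusted over the list alone. Fatty acid oxidation and peroxisome genes shifted upward by a median of 0.31 (adjusted p = 0.04, adjusted p = 0.4 with an estimated correlation), led by Cpt1a (0.66), which admits fatty acids to mitochondria, and Acaa2 (0.80). The NRF2 and oxidative stress list had a median of 0.11 (adjusted p = 0.04, adjusted p = 0.4 with an estimated correlation), with Hmox1 at 0.47 and Gpx1 at 0.34. Glycolysis and glucose transport shifted downward with a median of -0.06 (adjusted p = 0.029, adjusted p = 0.4 with an estimated correlation), although the glucose transporter Slc2a1 stood at 0.47 and Pgam2 at -0.44. The mTOR, AMPK and PI3K list had a median of -0.03 (adjusted p = 0.028, adjusted p = 0.2 with an estimated correlation), with Rptor at -0.19 and Mtor at -0.12. The 4 measured neuronal genes had a median of -0.16 (adjusted p = 0.04, adjusted p = 0.2 with an estimated correlation), with Gad1 at -0.16 and Hk1 at -0.17. Mapt (-0.09), Apoe (0.19) and Prkn (-0.10) did not pass. The choroid plexus gene Ttr, named after its values were seen, differed in the same samples by 5.21 ± 2.29 on the log2 scale (adjusted p = 0.36). With the choroid plexus level as a covariate, an alternative added after the data were seen, 2 of the 9 lists stayed called, the plaque-associated microglia list (median 0.26) and the lysosome list (median 0.22), and Cd68 stood at 0.55 ± 0.12 (adjusted p = 0.058). Cd68 kept its call with choroid plexus and Eomes covariates together. Cd68 was lost with thinned counts (adjusted p = 0.088) and a linear Ttr covariate (adjusted p = 0.14). It was also lost without WT 30 weeks replicate 1 or AD 30 weeks replicate 2 and with only the 6 samples of the age (adjusted p up to 0.31). The lists of neurons, glycolysis and NRF2 were lost with each of the 3 other scalings. The same held for fatty acid oxidation with median and housekeeping centring, and Toll-like receptor and NF-kB signalling with quantile normalization. The lists of neurons, fatty acid oxidation and NRF2 were lost without the 25% of probes with the lowest mean and with sex as a covariate, and those of fatty acid oxidation, NRF2 and mTOR with thinned counts. On omission of WT 30 weeks replicate 2, AD 30 weeks replicate 1 or AD 30 weeks replicate 2 the lists of neurons, fatty acid oxidation, mTOR and NRF2 were lost (adjusted p up to 0.26). Glycolysis was lost without WT 30 weeks replicates 1 or 3 or AD 30 weeks replicates 2 or 3 (adjusted p up to 0.22). Fatty acid oxidation was also lost without WT 30 weeks replicate 1, and NRF2 without AD 15 weeks replicate 1 or AD 50 weeks replicate 3. The count was 8 without WT 30 weeks replicate 2, 5 without AD 30 weeks replicate 1 and 4 without AD 30 weeks replicate 3, and 4 lists were called without AD 30 weeks replicate 2.

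At 50 weeks 8 genes rose and 2 fell in AD hippocampus (82 at an unadjusted p below 0.05). Cd68 rose from 308 ± 5.76 units in WT to 617 ± 17.4 in AD samples (2-fold, log2 change 1 ± 0.10, adjusted p = 9.6e-07 by limma). Ly86, a secreted partner of the Toll-like receptor homologue Cd180, rose from 452 ± 40.4 to 933 ± 131 units (1.04 ± 0.18, 2.05-fold, adjusted p = 0.0019). Ctss, the lysosomal protease cathepsin S, rose by 0.93 ± 0.18 (adjusted p = 0.0063) and Lag3, an inhibitory receptor of the immunoglobulin superfamily, by 0.88 ± 0.16 (adjusted p = 0.0021). Bcl2a1a, a BCL2 family gene whose probe was not checked against near-identical paralogs, rose by 0.91 ± 0.20 (adjusted p = 0.014), and the SLAM family receptor Cd84 by 0.82 ± 0.19 (adjusted p = 0.019). The remaining 2 were Hexb (0.64 ± 0.15, adjusted p = 0.019), a subunit of lysosomal hexosaminidase, and Rps6ka1 (0.73 ± 0.17, adjusted p = 0.025), which falls outside the naming rule and was chosen after its values were seen. Rgn fell from 24.6 ± 8.36 to 8.73 ± 5.20 units (-1.54 ± 0.35, adjusted p = 0.019) and Tcl1 from 29.0 ± 1.56 to 13.1 ± 5.22 (-1.16 ± 0.20, adjusted p = 0.0019). At these levels a sample held few counts, since 1 count was worth 1.87 to 2.73 units at this age. For each of these 10 genes the 3 AD samples lay beyond every WT sample, which chance gives for 10% of unselected genes with 3 samples against 3. The genes were called on these same samples, so the separation is no further evidence.

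**Figure D2:**
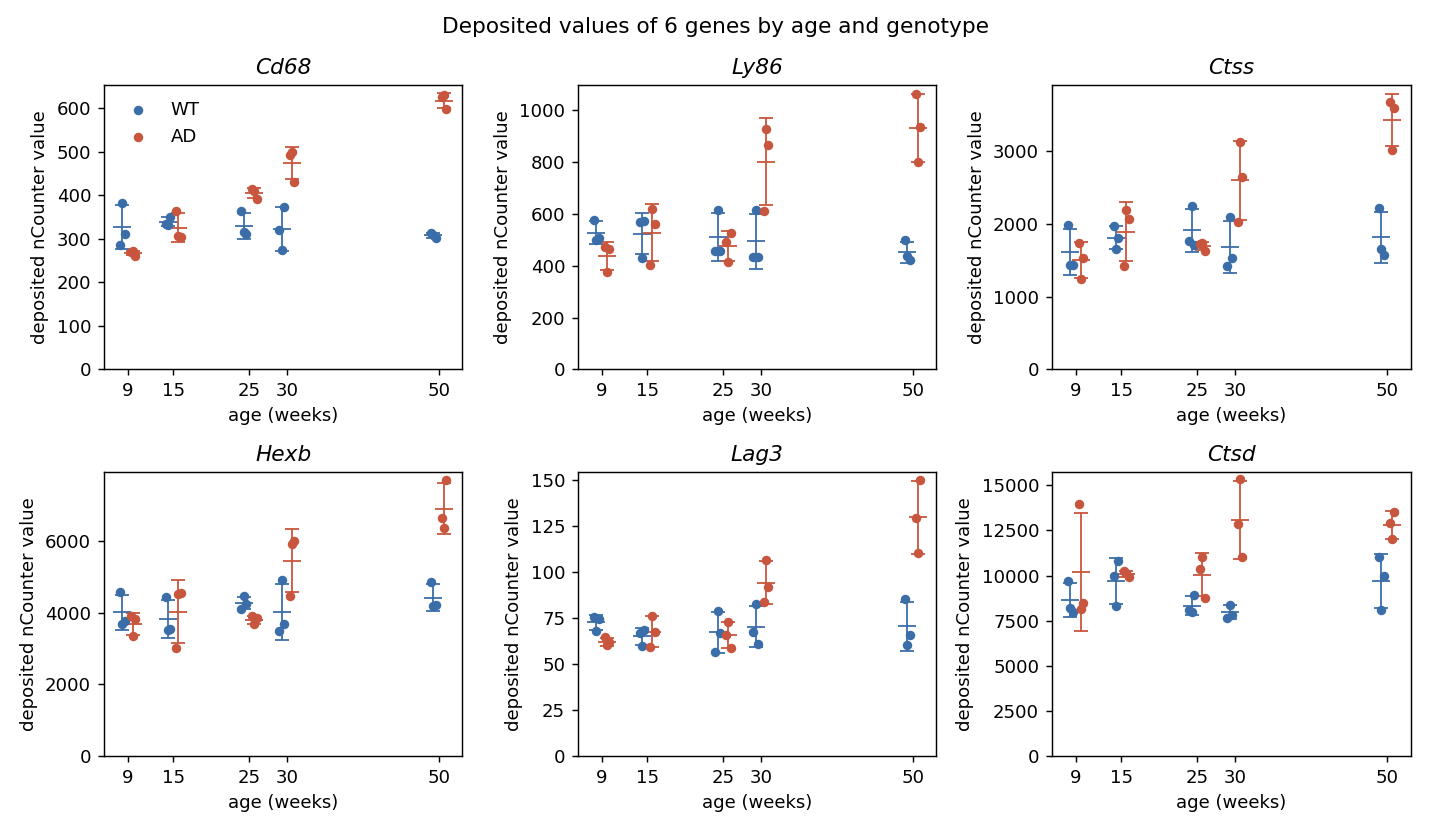
Deposited nCounter values (vertical axes, starting at 0) of Cd68, Ly86, Ctss, Hexb, Lag3 and Ctsd by age in weeks (horizontal axes) in WT (blue) and AD (red) samples. Points are single samples, and the horizontal marks and bars are the mean and SD of 3 samples. At 50 weeks mean Cd68 was 308 in WT and 617 in AD samples.

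The plaque-associated microglia list had 2 of 15 genes risen at 50 weeks, Cd68 and Ctss (5 adjusted over the list alone), with a median of 0.20 (adjusted p = 1.4e-06 by camera, adjusted p = 0.28 with an estimated correlation). The lysosome list had 3 of 16 risen, Cd68, Ctss and Hexb (3 adjusted over the list alone), with a median of 0.14 (adjusted p = 4.2e-05, adjusted p = 0.55 with an estimated correlation). Cytokine, chemokine and receptor genes shifted upward by a median of 0.37 (adjusted p = 0.044, adjusted p = 0.56 with an estimated correlation), with 0 of 7 called (3 adjusted over the list alone), the T cell chemoattractant Cxcl9 at 1.38 ± 0.39 and Ccl4 at 0.75 ± 0.24. Toll-like receptor and NF-kB signalling had a median of 0.05 (adjusted p = 0.043, adjusted p = 0.84 with an estimated correlation), with 0 of 11 called (2 adjusted over the list alone), Cd14 at 0.82 and Myd88 at 0.51. Complex I subunits shifted downward by a median of -0.06 (adjusted p = 0.044, adjusted p = 0.96 with an estimated correlation), with 0 of 17 called, Ndufb2 at -0.13 and Ndufb10 at -0.11. The TCA cycle list had a median of -0.09 (adjusted p = 0.044, adjusted p = 0.96 with an estimated correlation), with 0 of 21 called, the phosphatase Pdp1 at 0.65 and Pck1, an enzyme of gluconeogenesis, at -0.64. Neither of the last lists had a gene that passed when adjusted over the list alone (0 in each). The 26 T cell genes had a median of -0.03 (adjusted p = 0.99), and 0 of them passed (0 adjusted over the list alone). Mapt (0.05), Apoe (-0.03) and Prkn (-0.16) did not pass. By edgeR 6 genes passed, without Rgn, Tcl1, Cd84 and Rps6ka1. With only the 6 samples of the age Lag3 (adjusted p = 0.15), Cd84, Rgn, Tcl1 and Rps6ka1 were lost. Thinned counts lost Rgn, Tcl1, Rps6ka1 and Bcl2a1a. Quantile normalization lost Cd84, Rgn and Rps6ka1, and sample weights lost Rgn and Rps6ka1. The lists of complex I, the TCA cycle, Toll-like receptor and NF-kB signalling and cytokines were lost with median centring, with quantile normalization, and with choroid plexus and Eomes covariates, each of which left 2 lists. The same 4 were lost without WT 50 weeks replicate 2 or AD 50 weeks replicate 3 (2 lists), with an adjusted p up to 0.59 for complex I and 0.85 for the TCA cycle. Without the 25% of probes with the lowest mean, which include Cxcl9 and Ccl4, 3 lists were called. The Toll-like receptor and TCA cycle lists were lost there, and the cytokine list was not among the 3. With thinned counts the cytokine list was lost. Complex I and the TCA cycle were also lost without WT 50 weeks replicate 1, and the TCA cycle without AD 9 weeks replicate 1. The cytokine list was lost without WT 50 weeks replicate 3, AD 9 weeks replicate 1, AD 15 weeks replicate 1, AD 25 weeks replicate 2 or AD 50 weeks replicate 2 (adjusted p up to 0.37). Rps6ka1 was lost on omission of any of the 6 samples of this age. Without WT 50 weeks replicate 3 the count was 5, and Ctss (adjusted p = 0.068), Bcl2a1a (0.089), Cd84, Hexb and Rps6ka1 were lost. Cd84 (adjusted p up to 0.14) was also lost without WT 50 weeks replicate 2 or AD 50 weeks replicate 1. Hexb was lost without WT 50 weeks replicate 2 or AD 50 weeks replicates 1 or 3, Bcl2a1a without AD 50 weeks replicates 1 or 3, and Rgn without WT 50 weeks replicates 1 or 2 or AD 50 weeks replicate 3.

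Whether the genotypes diverged with age was tested as a difference of slopes. In 7 genes the slope was steeper in AD than in WT samples, and in 0 genes it was lower (57 at an unadjusted p below 0.05). The difference per 10 weeks was 0.32 ± 0.03 for Cd68 (adjusted p = 9.5e-07 by limma), 0.33 ± 0.06 for Ly86 (adjusted p = 0.0028), 0.26 ± 0.05 for Lag3 (adjusted p = 0.0061), 0.27 ± 0.06 for Cd84 and 0.26 ± 0.06 for Ctss (both adjusted p = 0.023). It was 0.40 ± 0.10 for Cd180 and 0.19 ± 0.05 for Hexb (both adjusted p = 0.049). Cd180 went from 66.2 ± 18.9 units at 9 weeks to 141.5 ± 18.8 at 50 weeks in AD samples and from 80.4 ± 3.98 to 73.4 ± 12.5 in WT samples. The plaque-associated microglia list (2 of 15 called, 3 adjusted over the list alone) had a median slope difference of 0.08 (adjusted p = 1.1e-05 by camera, adjusted p = 0.44 with an estimated correlation). For the lysosome list (3 of 16 called, 3 adjusted over the list alone) it was 0.03 (adjusted p = 0.00016, adjusted p = 0.48 with an estimated correlation). Cytokines, chemokines and receptors (0 of 7 called, 2 adjusted over the list alone) had 0.15 (adjusted p = 0.04, adjusted p = 0.48 with an estimated correlation), with Cxcl9 at 0.45 and Ccl2 at 0.35. Mapt (0.02), Apoe (0.00) and Prkn (-0.03) did not pass. The F test of any change of the genotype difference with age called Cd68 (adjusted p = 4.4e-05) and Ly86 (adjusted p = 0.032), with 44 genes at an unadjusted p below 0.05. It did not call Lag3 (0.11), Ctss (0.16), Tcl1, Serinc2 and Hexb (0.21 each), Cd180 (0.22), Cd84 (0.23) or Rps6ka1 (0.43). Without the 50-week samples 1 gene, Cd68, kept a slope difference and the F test called 0, while the plaque-associated microglia and lysosome lists remained called and the cytokine list did not. Cd180 and Hexb were lost with each of the 3 other scalings, without a variance trend, with sex as a covariate, by edgeR and with thinned counts. Thinned counts also lost Cd84 and Lag3, and Cd180 was lost with sample weights and with choroid plexus and Eomes covariates. Ly86 was lost from the F test with median centring and with sex as a covariate (adjusted p up to 0.1), and sample weights gave 5 genes there. Without the 25% of probes with the lowest mean 2 lists were called, and the cytokine list was not among them. The cytokine list was lost with thinned counts and with choroid plexus and Eomes covariates. It was lost without WT 9 weeks replicate 2, WT 15 weeks replicate 1, WT 50 weeks replicates 2 or 3, AD 9 weeks replicate 1, AD 15 weeks replicate 1, AD 25 weeks replicate 2 or AD 50 weeks replicate 3 (adjusted p up to 0.37), and 5 lists were called without AD 50 weeks replicate 2. The count was 3 without WT 9 weeks replicate 1, WT 50 weeks replicates 2 or 3, AD 9 weeks replicate 2 or AD 50 weeks replicate 1 and 4 without AD 50 weeks replicate 3. Cd84 (adjusted p up to 0.12) and Ctss (0.11) were lost in the first 5 of these and Ctss in the last. Cd180 and Hexb were each lost on omission of most samples. Ly86 was lost from the F test on omission of any of 17 samples (adjusted p up to 0.14), while 4 genes passed it without AD 50 weeks replicate 2.

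**Figure D3:**
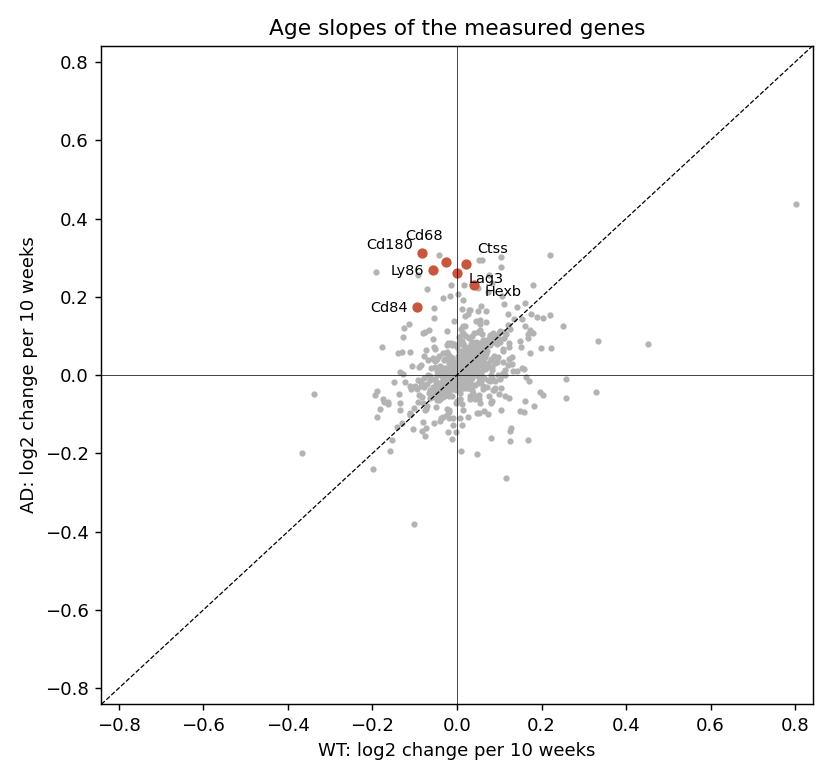
Change with age per 10 weeks on the log2 scale in WT (horizontal axis) and AD samples (vertical axis), with a grey point for each of the 768 probes and the line of equal slopes dashed. The 7 named genes in red, among them Cd68 and Ly86, had a steeper slope in AD samples.

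In WT hippocampus 19 genes rose and 3 fell with age (172 at an unadjusted p below 0.05). The most precise rise was in Npm1, the nucleolar protein nucleophosmin, from 9788 ± 183 units at 9 weeks to 13000 ± 532 at 50 weeks (0.09 ± 0.01 per 10 weeks, adjusted p = 5.3e-06 by limma). Tfrc, the transferrin receptor through which cells take up iron, fell from 4750 ± 376 to 2704 ± 139 units (-0.18 ± 0.02 per 10 weeks, adjusted p = 1.7e-05). The Tfrc probe is among the 22 housekeeping probes. Pdgfrb, a receptor of pericytes, fell from 83.1 ± 8.44 to 52.6 ± 5.82 units (-0.20 ± 0.04, adjusted p = 0.0055) and Mapk8ip1 fell by 0.06. Rises per 10 weeks were 0.26 for the fatty acid hydroxylase Cyp4a12a, whose probe was not checked against its near-identical paralog, and 0.22 for the Fc receptor Fcgr4. They were 0.10 for the mitochondrial ferredoxin Fdx1, 0.09 for Adal and 0.08 for the lipid phosphatase Pten. Complex I subunits shifted upward by a median of 0.03 (adjusted p = 0.03 by camera, adjusted p = 0.94 with an estimated correlation), with 2 of 17 genes risen (5 adjusted over the list alone), Ndufa6 by 0.06 and Ndufb7 by 0.05. The list of endothelium and mural cells shifted downward by a median of -0.09 (adjusted p = 0.026, adjusted p = 0.19 with an estimated correlation), with 1 of 3 genes fallen, Pdgfrb (2 adjusted over the list alone). Mapt (0.03), Apoe (0.04) and Prkn (0.06) did not pass. The split of calls moved with the scaling, to 5 rising and 2 falling with median centring and 5 rising and 16 falling with quantile normalization. Without the 50-week samples 4 genes passed, with Tfrc as the 1 gene shared, and the count was 10 without WT 50 weeks replicate 2, 11 without WT 50 weeks replicate 1, 13 without WT 9 weeks replicate 3 and 14 without WT 9 weeks replicate 1 or WT 15 weeks replicate 1. With sample weights 43 genes passed. Cyp4a12a and Fcgr4 were lost with median centring, by edgeR, with a choroid plexus or linear Ttr covariate and with thinned counts. Cyp4a12a was also lost with quantile normalization and Fcgr4 for 50 minus 9 weeks. Both probes lie among the 25% with the lowest mean. Adal, Pten, Ndufa6 and Ndufb7 were lost with median centring and quantile normalization, and Mapk8ip1 with median centring. Fdx1 and Ndufb7 were lost without a variance trend and with a choroid plexus covariate, and Ndufb7 with a linear Ttr covariate. Choroid plexus and Eomes covariates lost Cyp4a12a, Fdx1, Mapk8ip1 and Ndufb7, and thinned counts Fdx1, Adal, Pdgfrb, Mapk8ip1 and Ndufb7. On omission of 1 sample each of these genes but Pdgfrb was lost at least once, with an adjusted p up to 0.19, whereas Npm1, Tfrc and Pdgfrb were called on each omission. Complex I was lost with median centring, quantile normalization, choroid plexus and Eomes covariates and without the 25% of probes with the lowest mean (1 list in each). It was also lost without WT 9 weeks replicate 1, WT 15 weeks replicate 2 or WT 50 weeks replicate 1 (adjusted p up to 0.13). Neither list was called without WT 50 weeks replicate 2 (0 lists) or without the 50-week samples. In the latter case 15 of the 22 genes kept their direction, the others including Fcgr4 (-0.08), Npm1 (-0.01), Mapk8ip1 (0.02) and Ndufb7 (-0.02).

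In AD hippocampus 80 genes rose and 15 fell with age (191 at an unadjusted p below 0.05). Cd68 rose by 0.29 ± 0.02 per 10 weeks (adjusted p = 5.2e-09 by limma), from 267 ± 5.31 units at 9 weeks to 617 ± 17.4 at 50 weeks. The steepest rises were those of Cd180, Siglecf and Cybb (0.31 each), the asparaginase Aspg (0.30), and Bcl2a1a and Pdcd1 (0.29 each). Siglecf is a sialic acid receptor, Cybb the catalytic subunit of the phagocyte NADPH oxidase, and Pdcd1 the inhibitory receptor PD-1. Pdcd1 and Siglecf were low throughout, at 29.1 ± 3.16 and 30.8 ± 3.19 units at 50 weeks. The steepest falls were those of the scavenger receptor Cd163 (-0.38, from 30.7 ± 12.9 to 10.1 ± 3.73 units), Rgn (-0.26), the alcohol dehydrogenase Adh4 (-0.24), the ferredoxin reductase Fdxr (-0.20), the condensin subunit Ncaph (-0.16) and the protease Gzma (-0.14). Of the plaque-associated microglia list 9 of 15 genes rose (11 adjusted over the list alone), with a median of 0.09 (adjusted p = 5.1e-06 by camera, adjusted p = 0.37 with an estimated correlation), among them Cybb, Cd68, Ctss (0.28) and Ccl4 (0.28). Of the lysosome list 8 of 16 rose (9 adjusted over the list alone), with a median of 0.06 (adjusted p = 0.00066, adjusted p = 0.45 with an estimated correlation), among them Hexb (0.23) and Ctsz (0.17). Of these 8, Ctsz, Hexa and Neu1 were lost with median centring, quantile normalization and thinned counts. Gusb was also lost with median centring and Gns with thinned counts. Hexa, Neu1, Gusb and Gns were named after their values were seen, and Ctsz, Hexa and Gusb belong to both lists. In the autophagy and mitophagy list, which was not called (adjusted p = 0.23), 4 of 8 genes rose (4 adjusted over the list alone). These were Sqstm1, Atg101, Pik3r4 and Tbk1, and all but Sqstm1 lost their call with median centring, quantile normalization and thinned counts. Mapt (0.04), Apoe (0.05) and Prkn (0.03) did not pass. Of the genes that rose in each genotype, 13 were shared (2 for independent lists), among them Npm1, and of those that fell 1 was shared, Tfrc (0.059 for independent lists). With median centring most of the 13, though not Npm1, lost their WT call. Tfrc, and Hprt and Oaz1 of the 13, are among the 22 housekeeping probes, as is Gusb. Centring on these probes is thus no neutral check of the slopes. Hprt and Oaz1 were named after their values were seen. Both genotypes also share the lower depth of the 50-week samples, so the overlap does not by itself show shared ageing. Fdxr was lost with median centring, quantile normalization, a pseudocount of 10, sex as a covariate, sample weights, 50 minus 9 weeks, edgeR, choroid plexus and Eomes covariates and thinned counts. Gzma was lost with sex as a covariate, sample weights, edgeR and thinned counts. Each was also lost on omission of most samples (adjusted p up to 0.39 and 0.14). Rgn was lost with quantile normalization, sample weights, edgeR, thinned counts and without AD 9 weeks replicate 2 or AD 50 weeks replicate 3 (adjusted p up to 0.24). Adh4 was lost by edgeR, with thinned counts and without AD 50 weeks replicate 1 (0.058), and Cd163, Siglecf and Ncaph with thinned counts, Ncaph also without AD 50 weeks replicate 2 (0.13). Ctsz was lost with median centring, quantile normalization, 50 minus 9 weeks, thinned counts and without AD 9 weeks replicates 2 or 3, AD 15 weeks replicate 1 or AD 50 weeks replicates 1 or 3 (adjusted p up to 0.11). Cybb was lost without AD 9 weeks replicate 3 or AD 50 weeks replicate 1 (0.098). The split of calls moved to 27 rising and 13 falling with median centring and 29 rising and 32 falling with quantile normalization. Without the 50-week samples 3 genes passed, all among the 95, of which 85 kept their direction, the others including Rgn (0.07) and Fdxr (0.05), and the count was 57 without AD 50 weeks replicate 1.

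**Figure D4:**
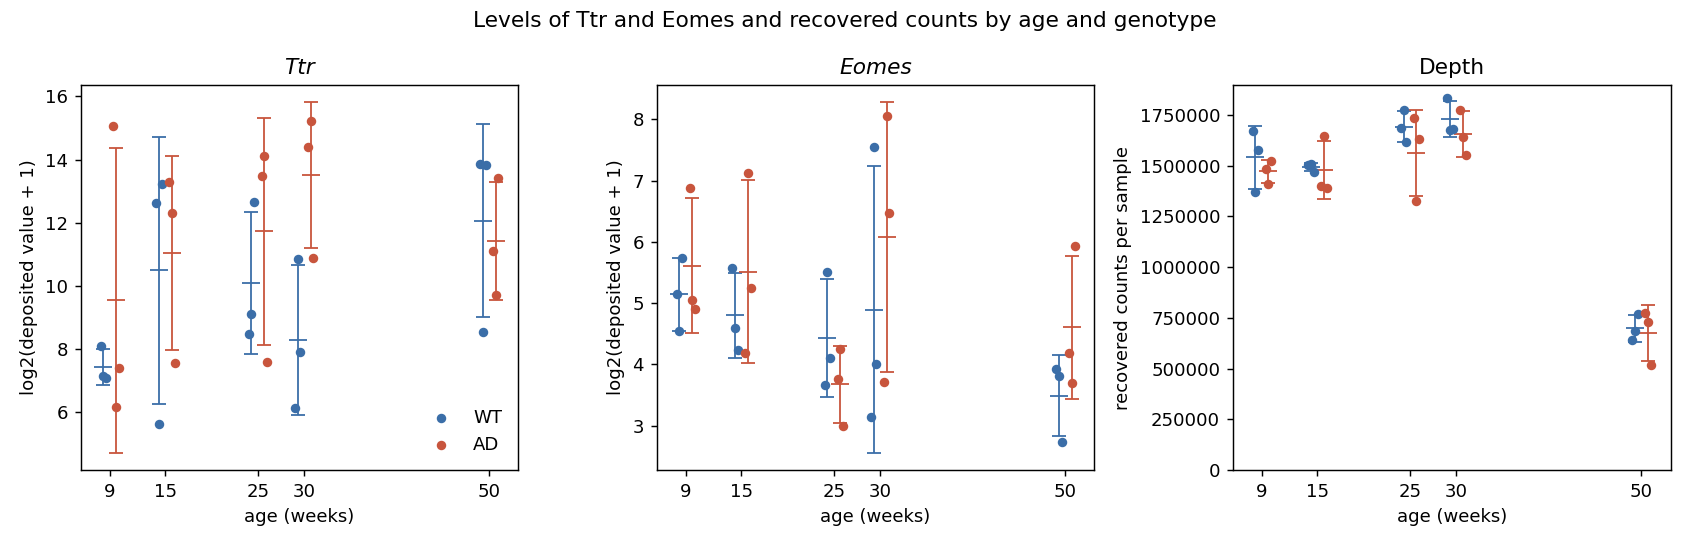
Levels of Ttr and Eomes as log2(deposited value + 1) and recovered counts per sample (vertical axes) by age in weeks (horizontal axes) in WT (blue) and AD (red) samples. Points are single samples, and marks and bars are the mean and SD of 3 samples. Ttr spanned 5.64 to 15.22 and Eomes 2.73 to 8.05, and the 50-week samples had the lowest counts.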

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

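The tests of the kind of microglial change, of background signal and of choroid plexus tissue in this part were chosen only after the results were seen. The genes given here drew attention because a test of the difference between ages or slopes called them. The difference between the slopes of AD and WT samples per 10 weeks was 0.40 for Cd180, 0.33 for Ly86, 0.32 for Cd68, 0.27 for Cd84, 0.26 for Lag3, 0.26 for Ctss and 0.19 for Hexb by limma. The F test of genotype and age gave an adjusted p of 4.4e-05 for Cd68 and 0.032 for Ly86, while Lag3 (0.11), Ctss (0.16), Hexb (0.21), Cd180 (0.22) and Cd84 (0.23) did not pass it. Cd180 (adjusted p up to 0.081) and Hexb (up to 0.11) lost their slope difference with each of the 3 other scalings, without a variance trend and with sex as a covariate, and neither passed by edgeR. At 9 weeks Cd68 had been lower in 3 of 3 AD samples without passing (-0.28 ± 0.10, adjusted p = 0.98), and at 50 weeks it was higher by 1 ± 0.10.

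Of 19 microglial genes, a list drawn up after the results were seen, 5 were called as higher in AD samples at 50 weeks and 14 did not pass, with estimates from -0.02 for Tlr2 to 0.94 for Cd180 among the latter. The rise could reflect more microglia of the same kind, a change within microglia, or a technical effect on the probes. From the mean change of 0.53, 2 genes departed after adjustment over the list, Ctss by 0.39 and Ly86 by 0.50, and among 7 abundant genes 6 departed from their mean, Cd68 by 0.37, Ctss by 0.30, Ly86 by 0.41, Fcrls by -0.26, Itgam by -0.36 and Ptgs1 by -0.47. The 7 abundant genes had mean log2 values of 8 or more, and 3 of the departing ones had not been called. Departures from the mean of the same genes balance out, so these 3 lie below it in part because called genes lie above it. The list was also drawn up after the results were seen, so background signal under low probes is not excluded as a cause of the unequal changes. The 2 genes that departed in the whole list were called genes, and expression of the listed genes in other cells was not measured. More microglia of the same kind are thus not excluded. Choroid plexus tissue as the whole cause is argued against, since 10 of the 10 genes called at 50 weeks stayed called with its level as a covariate, and a change within microglia remains an untested hypothesis.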

How the results depend on the processing

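The edgeR fit, the choroid plexus and Eomes covariates, the omission of the 50-week samples and the thinning of counts were chosen after results were seen, and the other alternatives before the data were examined. Counts of called genes at 9 and 15 weeks stayed 0 in every alternative run, and no called gene list turned its direction under another scaling. Values given here are numbers of genes or lists called, with the result described in the report in brackets. The cause of each move was not tested except where fewer samples or fewer counts entered by construction. Median centring gave 2 genes at 30 weeks (1), 7 for the WT slope (22), 40 for the AD slope (95) and 1 in the interaction test (2), with 1 list at 9 weeks (2), 0 at 15 weeks (2), 2 at 50 weeks (6), 1 for the WT slope (2) and 4 for the AD slope (2). Centring on housekeeping probes gave 1 list at 15 weeks and 5 at 30 weeks (9). Quantile normalization gave 61 genes for the AD slope and 4 in the interaction test, with 3 lists for the averaged difference (5), 1 at 9 weeks, 0 at 15 weeks, 5 at 30 weeks, 2 at 50 weeks, 1 for the WT slope and 4 for the AD slope. Without the 25% of probes with the lowest mean there were 2 genes at 30 weeks, with 0 lists at 9 weeks, 3 at 50 weeks and 1 for the WT slope. Without a variance trend 1 gene passed for the averaged difference (2). Sex as a covariate left 1 gene in the interaction test and 1 list at 15 weeks. Sample weights gave 12 genes for the averaged difference, 1 at 25 weeks (0), 31 at 30 weeks, 43 for the WT slope and 5 in the interaction test. With only the 6 samples of an age 0 genes passed at 30 weeks and 6 at 50 weeks (10). Pseudocounts of 10 and 0.5 and the contrast of 50 minus 9 weeks moved none of these counts by over 1.5 times.

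With an estimated correlation camera called 0 lists in each comparison (the averaged difference 0, each age 0, each slope 0 and their difference 0). The fry test called 2 lists for the averaged difference, 0 at 9 weeks, 0 at 15 weeks, 2 at 30 weeks, 1 at 50 weeks, 0 for the slope difference (3) and 9 for the AD slope. By edgeR 6 genes passed at 50 weeks. The choroid plexus covariate gave 0 genes at 30 weeks and 12 for the slope difference (7), with 3 lists for the averaged difference, 1 at 9 weeks and 2 at 30 weeks. Linear Ttr gave 0 genes at 30 weeks, 11 for the slope difference and 5 in the interaction test. With Eomes added there were 35 genes for the WT slope and 5 in the interaction test, with 2 lists for the averaged difference, 1 at 9 weeks, 1 at 15 weeks, 2 at 30 weeks, 2 at 50 weeks and 1 for the WT slope. Without the 50-week samples 0 genes passed for the averaged difference, 1 for the slope difference, 4 for the WT slope, 3 for the AD slope and 0 in the interaction test, with 1 list for the WT slope and 6 for the AD slope. The direction was then kept by 15 of the 22 genes of the WT slope and 85 of the 95 of the AD slope. Among the genes named in the report the slope had the opposite sign in WT for Fcgr4 (-0.08), Npm1 (-0.01), Mapk8ip1 (0.02) and Ndufb7 (-0.02) and in AD for Rgn (0.07) and Fdxr (0.05). Thinned counts gave 0 genes at 30 weeks, 6 at 50 weeks, 3 for the slope difference, 14 for the WT slope and 49 for the AD slope, with 8 lists for the averaged difference and 0 at 9 weeks.

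Omission of each sample in turn gave 1 to 4 genes for the averaged difference, 0 to 8 at 30 weeks, 5 to 15 at 50 weeks, 3 to 10 for the slope difference, 10 to 29 for the WT slope, 57 to 115 for the AD slope and 1 to 4 in the interaction test. The lists ranged from 4 to 7 for the averaged difference, 1 to 2 at 9 weeks, 0 to 3 at 15 weeks, 4 to 9 at 30 weeks, 2 to 6 at 50 weeks, 2 to 5 for the slope difference, 0 to 2 for the WT slope and 2 to 3 for the AD slope. At 25 weeks it gave 0 genes and 0 lists throughout. The extremes came at 30 weeks from WT 30 weeks replicate 1 or AD 30 weeks replicate 2 (0) and WT 30 weeks replicate 2 (8), and at 50 weeks from WT 50 weeks replicate 3 (5) and replicate 1 (15). Over all alternatives and named genes 5847 results were kept, 333 were weaker, 53 stronger, 6 reversed and 27 moved, and for lists 1065 were kept and 215 weaker. Most of these results came from omission of a single sample. Where that sample was of another age, the estimate at a single age could not change. Many of the named genes were uncalled to begin with, so the number kept is no measure of stability. A called gene was kept if its call and direction held. An uncalled gene was kept if it stayed uncalled and its estimate moved by less than its within-group SD, whatever the sign. Results of the F test have no direction and were kept if they stayed on the same side of the threshold. Moved genes, uncalled before, shifted by that SD or more or were called with the opposite sign.

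Samples of different groups share replicate numbers, and no pairing by number was seen. This cannot show that the numbers mark no litter or batch, which the labels do not state. Most of the 9 females were replicate 1 of their group, so the replicate block overlaps with sex as a covariate. Deviations from group means correlated by -0.004 on average between samples of the same number and by 0.0014 between others, 7 of 15 same-age pairs were above 0.1 (range -0.49 to 0.43), and 6 of 15 WT samples matched their own number best. With the replicate block there were 2 genes at 30 weeks and 1 in the interaction test, with 1 list at 9 weeks, where the list of complexes II to IV was lost (adjusted p = 0.05), and no other count moved by over 1.5 times. At 50 weeks Rgn, Tcl1, Rps6ka1 and Bcl2a1a were lost when counts were thinned.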

Other observations

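The tests of choroid plexus tissue and of depth in this part were chosen only after the results were seen, and those of a separate run and of other sample splits before. The genes named beside the choroid plexus and Eomes levels were also chosen after their values were seen. Samples differed widely in transcripts of the choroid plexus, the tissue that makes cerebrospinal fluid. Ttr, the thyroxine carrier made there, ran from 49 to 38173 units, 780-fold. Apart from Ttr and Folr1, 88 genes moved with this level within groups by limma, 73 upward and 15 downward. Per log2 unit of choroid level, Lepr, the leptin receptor, rose by 0.37 ± 0.045, the MHC class II gene H2-Aa by 0.34 ± 0.048 and the lactate transporter Slc16a8 by 0.24 ± 0.027. The thiolase Acaa2 rose by 0.14 ± 0.02, the tetraspanin Cd63 by 0.12 ± 0.016, the carnitine transferase Cpt1a by 0.10 ± 0.013, the protease Ctsd by 0.07 ± 0.0084 and the aldehyde dehydrogenase Aldh2 by 0.066 ± 0.0083. Cd68 did not move with it (0.0032 ± 0.011, adjusted p = 0.89).

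Samples also differed in Eomes, a transcription factor of glutamatergic neuron precursors and olfactory bulb neurons, which ran from 2.73 to 8.05 on the log2 scale. With the choroid level held, 159 genes moved with it by limma, 73 upward and 86 downward, and 15 of them were among the 88 (18.3 for independent lists). Per log2 unit of Eomes, Aspa, an oligodendrocyte enzyme that splits N-acetylaspartate, rose by 0.39 ± 0.061 and Gatm, which makes the precursor of creatine, by 0.27. Col6a1, a collagen chain, fell by 0.56, the retinol carrier Rbp4 by 0.34 ± 0.043 and the transcription factor Nr2f1 by 0.22. The neuronal glucose transporter Slc2a3 (-0.17) and the enzymes Pkm (-0.081) and Aldoa (-0.068) fell as well. Cd68 did not pass (-0.051, adjusted p = 0.08).

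The genotype differences at 30 weeks could come in part from choroid plexus tissue, since Ttr had a higher estimate in AD samples at that age without passing (5.21 ± 2.29, adjusted p = 0.36 by limma). Cd68 stood at 0.55 ± 0.12 with the choroid level as a covariate and at 0.56 ± 0.10 without it, so the estimate argues against choroid tissue as its source, although its call was lost because the SE widened. With choroid plexus and Eomes covariates together the call was kept. For the 95 genes other than Cd68, Ttr and Folr1 at an unadjusted p below 0.05 at this age a median of 57.6% of the change was left (quartiles 41 and 85.1%), between the limits set for either reading, and Ctsd went from 0.70 ± 0.15 to 0.39 ± 0.09. How much of the 30-week list shifts comes from dissection and how much from genotype is thus undecided.

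The age slopes might reflect how the 50-week samples were measured, since they were read at less depth. With all samples thinned to the lowest total the median slope of the called genes was 99.4% of its size in WT and 100% in AD, but random thinning keeps the expected proportions of genes, so this decides nothing about depth. A first form of this test, by the number of calls left (14 of 22 and 49 of 95), had decided nothing either and was replaced once its outcome was seen, so depth stays open. For 55 genes that set the 50-week WT samples apart, AD samples of 9 to 30 weeks had a median slope of 0.027 in the same direction (40 of 55 genes, permutation p = 0.045, adjusted over the 2 tests 0.09), and the limit set beforehand, 0.05 for a single test, was too loose for 2. For 91 such genes of the AD samples the WT slope was -0.0015 (45 of 91 genes, permutation p = 0.61), so a separate run of the 50-week samples is neither shown nor excluded.

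Calls were also counted after other splits of the samples into groups of the same size. Within an age there are only 10 splits, the real one included, too few for a share under 5%. Genes called by the real and by the highest other split were 0 and 0 at 9 weeks (10 splits called as many), 0 and 0 at 15 weeks (10), 0 and 0 at 25 weeks (10), 1 and 58 at 30 weeks (2) and 10 and 9 at 50 weeks (1). For lists they were 2 and 2 at 9 weeks (2), 2 and 4 at 15 weeks (4), 0 and 2 at 25 weeks (10), 9 and 6 at 30 weeks (1) and 6 and 8 at 50 weeks (3). The split with 58 genes at 30 weeks set samples apart by Eomes, with a difference of 3.74 on the log2 scale against 1.18 for the real split. With 100 splits, the real one included, the averaged difference had 2 genes against 73 (5 splits as many) and 5 lists against 6 (6), so chance is not excluded for either. The slope difference had 7 genes against 40 (2) and 3 lists against 8 (19), and the interaction test 2 genes against 148 (2). The WT slope had 22 genes against 1 (1) and 2 lists against 7 (22), and the AD slope 95 genes against 87 (1) and 2 lists against 6 (46). Fewer than 5% of splits called as many genes for the slope difference, the interaction test and both slopes, which did not hold for lists. This limit was set for a single count and was not adjusted over the counts tested. For the slope difference and the interaction test another split called 40 and 148 genes, so chance is not excluded for either. For both slopes no other of the 100 splits called as many genes as the real one. Splits that call several times the real number, 58, 73, 40 and 148 genes, point to a structure among the samples, which was compared with a measured level only for the split with 58.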
